A study of Mus musculus with 9 samples.

How the data were processed

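The deposited values used here are counts of sequencing reads per gene, 1 table for each of 9 libraries. Per the labels' protocols, total RNA was extracted with Trizol from mouse gastrocnemius, treated with DNase and made into mRNA libraries from 250 ng with a KAPA kit. Per the submitters' processing notes, reads were trimmed with cutadapt 2.10, aligned to mm10 with STAR 2.7.5a and counted per gene with HTSeq 0.12.4, and the submitters' own comparisons used DESeq2 1.30.0. The annotation release and the strand setting of the counting are not given in the sources used here. Each table held 55401 genes and 5 rows that name no gene. Those rows held 16.8% to 18.3% of the reads and were left out of library sizes and tests. Gene names and coordinates (GRCm38, the assembly of mm10) came from GENCODE M21, matched by gene identifier without its version: 55141 identifiers matched, 54349 of them with the same version, and 260 did not.

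Of 30602 genes with at least 1 count, 18514 passed edgeR's expression filter and were tested. Libraries held 44603618 to 76970849 counts. The 9 libraries were fitted together with edgeR 4.0.16 in R 4.3.3 (TMM scaling, quasi-likelihood F test, robust, 1 mean per group). The spread of a gene was taken to be the same in all groups, so every library enters every comparison. The biological coefficient of variation was 0.232 and 6 residual degrees of freedom remained. P-values were adjusted by the Benjamini-Hochberg method within each of the 3 comparisons, with an adjusted p under 0.05 as the threshold for a call, so every adjusted p of a gene is from edgeR unless another tool is named. The standard error of a log2 fold change is its size divided by the square root of F. Values in CPM are counts scaled to the TMM-adjusted library size, as mean ± SD over 3 libraries. Intervals and floors on counts (3 counts over a group for a gene at 0, and in list medians for a gene with at most 3) cover counting error only. The labels do not say that the libraries come from separate animals, so p-values measure the spread between libraries.

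Gene lists were written before the data were examined, as were the comparisons, the main test, the alternatives and the rule for naming genes. There were 40 lists and 120 list tests, adjusted together. Lists were tested with camera of limma 3.58.1 at a preset correlation between members of 0.01, again with the correlation estimated from the data, and with fry. Counts of list members are given over all tested genes and adjusted over the list alone. The rule names Mbnl1, Mbnl2 and Mbnl3 and up to 4 members of each list, ordered by p-value. It also names, per direction, the 12 called genes with the greatest change among protein-coding genes that have a mean of at least 1 CPM and groups that do not overlap, leaving out predicted gene models. Where fewer than 10 genes meet this, it names the 10 genes with the smallest p-values under the same conditions on symbol, biotype and CPM. Genes outside it were chosen after their values were seen: members named to complete a small count or because they moved against their list (Xbp1, Pnpla2, Usp2, Cxcl13, Pgam2, Slc2a1, Npas2, Pln and, against AAV-GFP, Cxcl14, Sgca, Pax7, Myf6, Myog and Vim) and genes of polyamine metabolism.

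The procedure was tested on simulated data drawn from the means and library sizes of these libraries. Each simulated gene had the same spread in all groups and was independent of the others. The simulation thus lacked the wider spread and the correlated genes of the AAV-GFP libraries, and its shares may not carry over to these data. At a 2-fold change it recovered 52.1%, 51.5% and 44% of changed genes for AAV-GFP against saline, AAV-GFP-MBNL1Δ against saline and AAV-GFP-MBNL1Δ against AAV-GFP, and at a 4-fold change 76%, 78% and 90.8%. False calls made up 6.11%, 7.86% and 4.32% of calls over 18247, 18280 and 18295 genes.

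The alternatives were other scalings (DESeq2's size factors, upper quartile), no filter or a stricter one (1 CPM in 3 libraries), DESeq2 1.42.0, limma-voom, a fit that is not robust, a fold threshold (log2 above 0.58), only the 2 groups compared, the replicate number as a block, removal of mitochondrial and the 10 most abundant genes, and leaving out each library in turn. Added after the data were seen were limma-voom with a quality weight per library, autosomal genes alone and the genes shared between comparisons under each setting. Splicing was not analysed here, since counts per gene do not hold it, and reads of the vectors were not measured, since the tables hold mouse genes alone. Some results are not reported here.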

Results

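RNA was sequenced from the gastrocnemius, a calf muscle, of wild-type FVB mice aged 2 to 3 months. The muscle had been injected 7 weeks before collection with saline, with an adeno-associated virus vector carrying green fluorescent protein (AAV-GFP), or with a vector that also carried a shortened form of MBNL1 (AAV-GFP-MBNL1Δ). Each of the 3 groups held 3 libraries. MBNL1 is an RNA-binding protein that controls alternative splicing in muscle and that is bound by the expanded CUG repeats of myotonic dystrophy, and the series title describes a decoy protein for such repeats. In normal muscle, the design compares the control vector with saline and the decoy vector with both. Counts assigned to genes came to 72825219, 69209598 and 76970849 in saline replicates 1 to 3. They came to 62122712, 63732069 and 44603618 in the AAV-GFP replicates and to 69963556, 58667692 and 74865772 in the AAV-GFP-MBNL1Δ replicates. The first principal component of log2 expression held 60.2% of the variance and placed AAV-GFP 1, 2 and 3 at 61.7, 132.3 and −16.6, with the saline libraries between −59.2 and −50 and the AAV-GFP-MBNL1Δ libraries between −23.8 and 8. The second component held 22.2% and placed the AAV-GFP-MBNL1Δ libraries between −53.3 and −46.9 and the other 6 between 15.5 and 28.1. AAV-GFP 2 also had the lowest share of counts in its 10 most abundant genes, 17.7% against 23.6% to 27.7% elsewhere, and the lowest share of mitochondrially encoded transcripts, 9.68% against 13.3% to 15.4%.

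Mbnl1 (chromosome 3, 60472830 to 60629750 in mm10) was detected in every library, at 540 ± 83.2 CPM (counts scaled to library size; mean ± SD, n = 3) in saline, 436 ± 71.2 CPM in AAV-GFP and 642 ± 68.1 CPM in AAV-GFP-MBNL1Δ. Its log2 fold change was 0.25 (SE 0.17, adjusted p = 0.398) for AAV-GFP-MBNL1Δ against saline and −0.31 (SE 0.17, adjusted p = 0.295) for AAV-GFP against saline. Against AAV-GFP, Mbnl1 rose by 0.56 in AAV-GFP-MBNL1Δ (SE 0.17, adjusted p = 0.0475), a call that ended when any 1 of the 9 libraries was left out (adjusted p from 0.0513 to 0.135). Gene counts do not separate transcripts of the vector from those of the mouse's own Mbnl1. Mbnl2 (chromosome 14) stood at 355 ± 39.9, 293 ± 52.9 and 303 ± 23.3 CPM in saline, AAV-GFP and AAV-GFP-MBNL1Δ, with adjusted p of 0.296, 0.39 and 0.828 for the AAV-GFP, AAV-GFP-MBNL1Δ and vector-to-vector comparisons. Mbnl3 (chromosome X) was scarce, at 0.07 ± 0.0217, 0.731 ± 0.716 and 0.131 ± 0.0633 CPM. It fell by 2.53 on the log2 scale between AAV-GFP and AAV-GFP-MBNL1Δ (SE 0.76, adjusted p = 0.0477), a call that was kept without AAV-GFP 3 and ended without any other library (adjusted p up to 0.156).

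The sex-linked genes, measured as a check of the samples, separated the AAV-GFP-MBNL1Δ libraries from the other 6. Xist, the noncoding RNA that silences an X chromosome in female cells, was at 105 to 136 CPM in the saline and AAV-GFP libraries and at 0.0902, 0.0182 and 0.03 CPM in AAV-GFP-MBNL1Δ 1, 2 and 3. The Y-linked Ddx3y was at 82.7, 84.6 and 84 CPM in AAV-GFP-MBNL1Δ and at 0.409 to 0.693 CPM in saline. Eif2s3y, Uty and Kdm5d, also on the Y chromosome, were at 50.5 to 60.4, 26.7 to 29.6 and 12.4 to 18.2 CPM in AAV-GFP-MBNL1Δ. In saline Eif2s3y had 0 counts in all 3 libraries, which allows up to 0.0141 CPM over the group. AAV-GFP 1 differed from AAV-GFP 2 and 3 in these genes, with 2.58 CPM of Ddx3y, 1.11 CPM of Eif2s3y, 0.741 CPM of Uty and 0.0741 CPM of Kdm5d. The AAV-GFP-MBNL1Δ libraries thus had the expression pattern of males, and the other 6 that of females apart from low Y-linked reads in AAV-GFP 1. The labels used here give no sex. Sex and AAV-GFP-MBNL1Δ therefore cannot be separated in any comparison that includes that group.

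**Figure D1:**
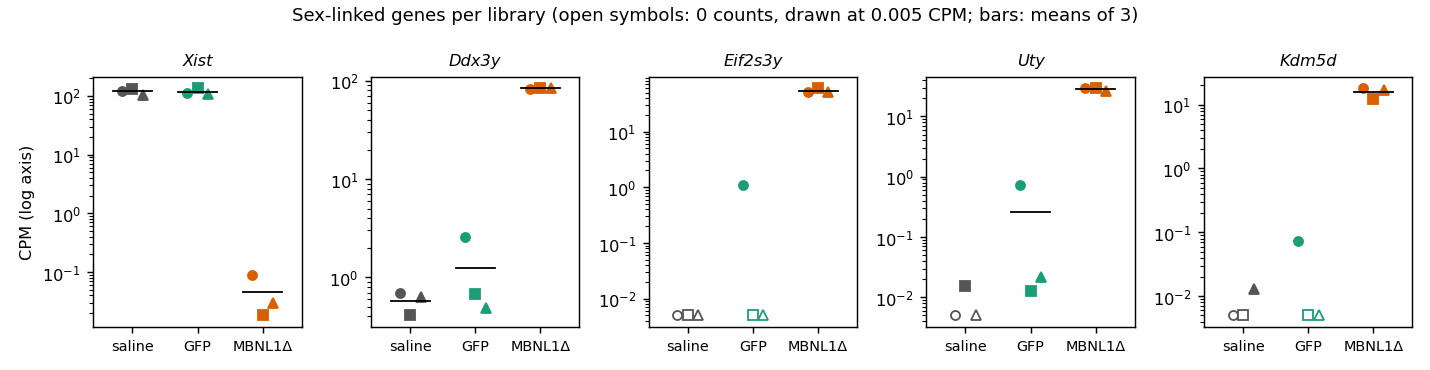
CPM (log axis) of Xist and 4 Y-linked genes in each of the 9 libraries, with circles, squares and triangles for replicates 1, 2 and 3 of saline (grey), AAV-GFP (green) and AAV-GFP-MBNL1Δ (orange). Xist stood at 105 CPM or more in the saline and AAV-GFP libraries and below 0.1 CPM in the AAV-GFP-MBNL1Δ libraries, and the Y-linked genes showed the opposite split.

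AAV-GFP against saline showed what the control vector was accompanied by in normal muscle. Transcripts of T cells, B cells, macrophages, antigen presentation and the interferon response were higher in all 3 AAV-GFP libraries as list medians, and no single gene passed the test. The chemokine Cxcl9, which attracts T cells, was at 133 ± 146 CPM (mean ± SD, n = 3) against 0.279 ± 0.223 CPM in saline, and Cxcl10, a ligand of the same receptor, at 16.8 ± 13.6 against 0.115 ± 0.0367 CPM. Lck, the kinase that starts T-cell receptor signalling, was at 7.48 ± 7.06 against 0.135 ± 0.0262 CPM, and Il2rb, a receptor chain for interleukins of lymphocytes, at 12.1 ± 12.4 against 0.118 ± 0.0855 CPM. Ncr1, an activating receptor of natural killer cells, was at 3.78 ± 3.41 against 0.0703 ± 0.0428 CPM, and Jchain, which joins secreted antibodies, at 366 ± 451 against 0.405 ± 0.187 CPM. Iigp1 and Irgm2, interferon-induced GTPases that act on vacuoles of intracellular pathogens, were at 780 ± 622 and 432 ± 283 CPM against 17.1 ± 12.8 and 25 ± 10.5 CPM. Irf9, the DNA-binding part of the complex that type I interferon activates, was at 26.5 ± 9.02 against 8.63 ± 2.31 CPM. The MHC class II chain H2-Aa was at 333 ± 366 against 14.9 ± 2.5 CPM, the immunoproteasome subunit Psmb8 at 72.7 ± 70.9 against 7.04 ± 2.37 CPM, and the macrophage genes Ctss and Mpeg1 at 237 ± 296 and 183 ± 211 against 6.93 ± 1.61 and 10.4 ± 1.77 CPM. Each of these 13 genes had an adjusted p of 0.0841, and without AAV-GFP 3 each passed, with adjusted p from 0.00156 (Cxcl10) to 0.00293 (Mpeg1).

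As lists, 14 stood above the other genes by camera, and 10 of them are described here, with cell cycle genes and the unfolded protein response beside the immune groups. The other 4 were granulocytes and mast cells (camera adjusted p = 0.0123, and adjusted p = 0.592 with an estimated correlation), extracellular matrix (6.48e-05, and adjusted p = 0.664 with an estimated correlation), immediate early genes (7.77e-04, and adjusted p = 0.643 with an estimated correlation) and cytosolic ribosomal proteins (0.00222, and adjusted p = 0.743 with an estimated correlation). The ribosomal list lost its call without AAV-GFP 2 or 3 (0.147 and 0.223). The median log2 fold change of the 10 lists was 5.57 for T cells and cytotoxic lymphocytes (adjusted p = 4.3e-32), 6.76 for B and plasma cells (3.61e-14), 3.85 for chemokines and cytokines (3.05e-19), 3.06 for monocytes and macrophages (1.51e-19), 4.05 for MHC class II (4.18e-16), 2.58 for MHC class I presentation (1.39e-18) and 1.98 for interferon-stimulated genes (1.72e-35). It was 1.46 for complement (1.13e-08), 2.72 for cell cycle genes (1.39e-12), among them the proliferation marker Mki67 at 18.3 ± 18.6 against 1.03 ± 0.25 CPM (adjusted p = 0.0855; 0.00156 without AAV-GFP 3), and 0.49 for the unfolded protein response (4.41e-04). These calls were lost with the correlation between members taken from the data (adjusted p = 0.592 with an estimated correlation, for each of the 10). Adjusted over the list alone, 30 of 30 T-cell genes, 19 of 20 B-cell genes, 23 of 25 chemokines, 26 of 27 macrophage genes, 15 of 16 MHC class II genes, 19 of 19 MHC class I genes, 43 of 44 interferon-stimulated genes, 14 of 19 complement genes, 22 of 26 cell cycle genes and 9 of 23 genes of the unfolded protein response were higher, and 0 over all genes tested. At most 3 counts in a group were held by 3 T-cell, 3 B-cell and 2 chemokine genes, so the size of their change is uncertain. With 3 counts set there, the medians of these lists stayed at 5.57, 6.76 and 3.85. The AAV-GFP libraries differed in size of the difference. The interferon list stood 1.48, 2.94 and 0.94 above the saline mean in replicates 1, 2 and 3 and the T-cell list 4.63, 6.06 and 2.30. The B-cell list stood 5.62, 6.86 and 1.13 above it, and the cell cycle list 2.23, 3.64 and 0.23. AAV-GFP 2, the highest in each, was also the library with 17.7% of counts in its 10 most abundant genes.

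Genes of contraction and energy supply were lower as lists in AAV-GFP than in saline, most of all in AAV-GFP 2. The median log2 fold change was −0.33 for fast fibre genes (adjusted p = 2.57e-05 by camera, 0.614 with an estimated correlation), −0.29 for excitation-contraction coupling (4.02e-06, and adjusted p = 0.592 with an estimated correlation). It was −0.34 for the sarcomere and Z-disc (1.15e-05, and adjusted p = 0.599 with an estimated correlation) and −0.27 for glycolysis and glycogen (4.82e-05, and adjusted p = 0.599 with an estimated correlation). It was −0.20 for nuclear-encoded oxidative phosphorylation (6.35e-07, and adjusted p = 0.7 with an estimated correlation), −0.37 for mitochondrially encoded mRNAs (1.59e-04, and adjusted p = 0.659 with an estimated correlation) and −0.28 for genes whose splicing MBNL proteins regulate (6.35e-07, and adjusted p = 0.592 with an estimated correlation). The other 4 of the 11 lists called lower were the circadian clock (0.00258, and adjusted p = 0.592 with an estimated correlation), fatty acid oxidation (0.00137, and adjusted p = 0.7 with an estimated correlation), endothelial cells (median −0.21, 0.00682, and adjusted p = 0.687 with an estimated correlation) and smooth muscle and pericytes (0.0245, and adjusted p = 0.7 with an estimated correlation). Endothelial cells (0.0634), fatty acid oxidation (0.113) and smooth muscle (0.193) lost their calls without AAV-GFP 2, which left 8 lists, and smooth muscle also without saline 3 (0.116). No member of these 11 lists passed, either over all genes or adjusted over the list alone. The calcium pump of fast fibres, Atp2a1, was at 21200 ± 6190 CPM against 31800 ± 3940 CPM in saline (adjusted p = 0.215). The fast myosin Myh4 was at 37800 ± 10300 against 56600 ± 11900 CPM (adjusted p = 0.242). The calcium release channel Ryr1 was at 2900 ± 862 against 4340 ± 341 CPM (0.199) and the giant thin-filament protein Neb at 4380 ± 1270 against 6450 ± 758 CPM (0.204). The decrease was largest in AAV-GFP 2, where the fast fibre list stood 0.68 below the saline mean in log2 terms (−0.68, against −0.25 and −0.09 in AAV-GFP 1 and 3 and 0.15, 0.04 and −0.21 in saline 1, 2 and 3) and where mitochondrially encoded transcripts made up 9.68% of counts. In AAV-GFP 3 the median stood at 0.06 for oxidative phosphorylation, 0 for mitochondrially encoded mRNAs, −0.03 for the sarcomere, −0.07 for glycolysis and −0.14 for excitation-contraction coupling. In AAV-GFP 2 endothelial cells, Schwann cells and smooth muscle also stood lower (−0.47, −0.55 and −0.46), while fibroblasts stood at 0.13, extracellular matrix at 0.96 and T cells at 6.06. CPM are shares of a library, so these values do not separate levels within muscle fibres from the mix of cells.

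With edgeR's quasi-likelihood test, 0 genes passed between AAV-GFP and saline (lowest adjusted p = 0.0841), while 2889 higher and 1176 lower genes had an unadjusted p under 0.05. Limma-voom called 0 genes, DESeq2 1619 higher and 86 lower, and limma-voom with a quality weight per library, an alternative added after the data were seen, 3078 higher and 2386 lower. The 3 AAV-GFP libraries set this number: without AAV-GFP 3, 2907 genes were higher and 355 lower, and without AAV-GFP 2, 5 were higher and 0 lower. All 3 libraries of one group lay above all 3 of the other in 27.1% of the 18514 genes tested, where chance gives 10% on average. Genes that move together can shift this share far from 10% under any split, so the gap is not a test.

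**Figure D2:**
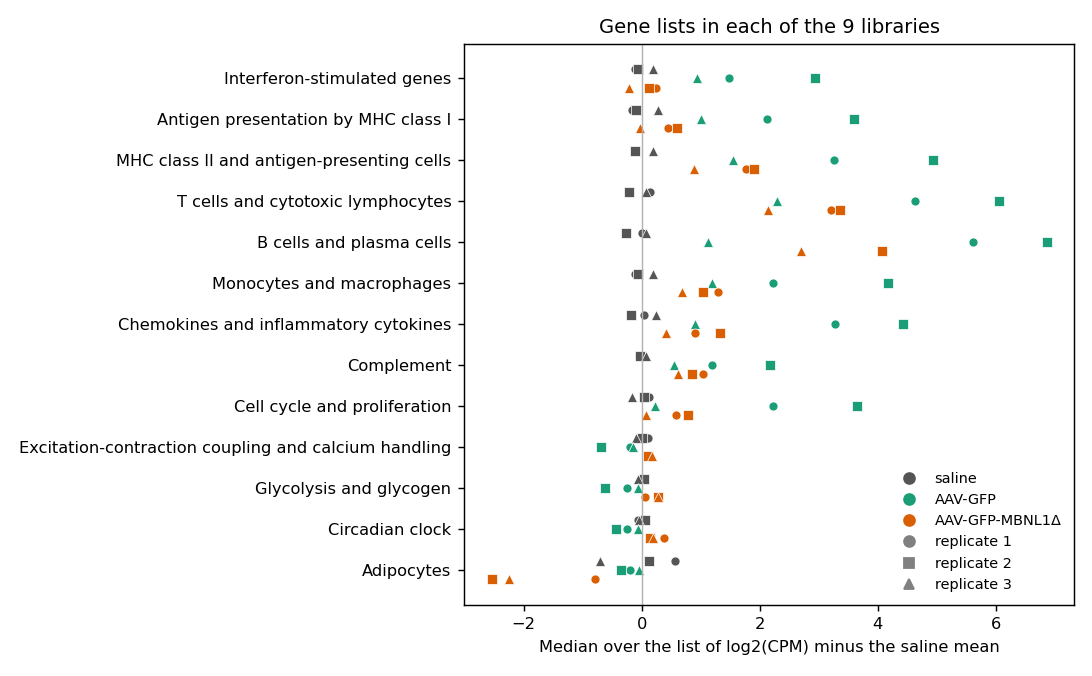
Median log2 level of the measured members of gene lists in each library, relative to the mean of the 3 saline libraries (circles, squares and triangles for replicates 1, 2 and 3 of saline in grey, AAV-GFP in green and AAV-GFP-MBNL1Δ in orange). The interferon-stimulated genes stood 0.94 to 2.94 above the saline mean in AAV-GFP and between −0.22 and 0.25 in AAV-GFP-MBNL1Δ, and the adipocyte genes stood between −2.54 and −0.79 in AAV-GFP-MBNL1Δ.

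AAV-GFP-MBNL1Δ against saline gave 882 genes that rose and 852 that fell. With only these 2 groups fitted, 2303 rose and 2281 fell. Trnp1 (chromosome 4, 133491100 to 133498550), which codes for a nuclear protein first described in neural progenitors, rose from 0.0741 ± 0.0383 to 31.9 ± 6.96 CPM (log2 fold change 8.69, SE 0.51, adjusted p = 0.000186). Themis3 rose by 7.57 (SE 0.57, adjusted p = 0.000351) and Slc15a5, of the peptide transporter family, from 0.653 ± 0.149 to 67.2 ± 4.98 CPM (6.68, SE 0.60, adjusted p = 0.00084). The complement component C7, part of the membrane attack complex, rose by 4.55 (SE 0.31, adjusted p = 0.000226). On the other side, Lep, the adipocyte hormone leptin, fell by 4.69 (SE 0.67, adjusted p = 0.00619), Klhdc7a by a log2 fold change of −4.08 (SE 0.54, adjusted p = 0.00401) and Pnpla3, a lipid-droplet protein that insulin induces, by −3.67 (SE 0.43, adjusted p = 0.0025). Mybph, a myosin-binding protein, fell from 370 ± 77.3 to 48.2 ± 18.8 CPM (−2.94, SE 0.28, adjusted p = 0.000865). Each of these 8 calls was kept with any 1 of the 9 libraries left out. Of the called genes, 859 that rose and 804 that fell lie on autosomes. The numbers were smaller without any 1 saline library (327 higher and 254 lower, 287 and 221, and 387 and 392 without replicates 1, 2 and 3), without AAV-GFP 1 (607 and 534) or without AAV-GFP-MBNL1Δ 1, 2 or 3 (466 and 354, 488 and 318, 286 and 214), and larger without AAV-GFP 2 (1933 and 2114). In the libraries compared, Xist was at 105 to 130 CPM in saline and at 0.0182 to 0.0902 CPM in AAV-GFP-MBNL1Δ, so these calls compare vector and sex at once.

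Some lymphocyte genes and chemokines rose in AAV-GFP-MBNL1Δ against saline, while interferon-stimulated genes were not called as a list. Ighm, the heavy chain of IgM, rose from 135 ± 40.2 to 825 ± 104 CPM (log2 fold change 2.61, SE 0.24, adjusted p = 0.000646), with all 9 refits that leave out 1 library keeping the call, and immunoglobulin genes may share reads with related segments. Ighm did not follow the B-cell list in AAV-GFP. There the list median was 6.76 against saline and Ighm stood near its saline level, so its rise here cannot be read as more B cells. Cxcl9 rose to 15.1 ± 7.77 CPM (5.75, SE 1.26, adjusted p = 0.0291) and Cxcl10 to 2.91 ± 1.45 CPM (4.65, SE 0.94, adjusted p = 0.0217). Il2rb rose to 2.83 ± 1.12 CPM (4.56, SE 1.02, adjusted p = 0.0314) and Lck to 2.15 ± 0.786 CPM (3.96, SE 0.89, adjusted p = 0.0311). The calls of Cxcl9, Cxcl10, Il2rb and Lck ended without any 1 saline library and without AAV-GFP-MBNL1Δ 1 or 2, those of Cxcl9, Il2rb and Lck also without AAV-GFP-MBNL1Δ 3 and those of Il2rb and Lck also without AAV-GFP 1 (adjusted p up to 0.116, 0.0887, 0.122 and 0.12). Il15, a cytokine that muscle itself makes, fell from 16.8 ± 0.431 to 5.86 ± 0.906 CPM (−1.52, SE 0.13, adjusted p = 0.000469) and kept its call in all refits. Of 25 chemokines and cytokines 5 rose (Cxcl9, Cxcl10, Cxcl14, Ccl5 and Cxcl13, the last named after its value was seen) and 1, Il15, fell. For the chemokine list, adjustment over the list alone gave 6 higher and 1 lower. The chemokine median was 1, with a camera adjusted p of 0.00238 (adjusted p = 0.7 with an estimated correlation). Without saline 2 or 3 or AAV-GFP-MBNL1Δ 1 or 2 none rose, 1 without saline 1 or AAV-GFP-MBNL1Δ 3, 2 without AAV-GFP 1 and 9 without AAV-GFP 3. Of 30 measured T-cell genes 6 rose and 24 did not pass. For the T-cell list, adjustment over the list alone gave 23 higher. The T-cell median was 3.52, with a camera adjusted p of 4.84e-13 (adjusted p = 0.592 with an estimated correlation). The 6 became 0 without any 1 saline or AAV-GFP-MBNL1Δ library or AAV-GFP 1, and 21 and 23 without AAV-GFP 2 and 3. Of 20 B-cell genes, Ighm, Ighd, Igha and Jchain rose. For the B-cell list, adjustment over the list alone gave 13 higher, with Xbp1, named after its value was seen, lower. The B-cell list had a camera adjusted p of 2.02e-10 (adjusted p = 0.592 with an estimated correlation). The B-cell median was 4.74, or 4.29 with the 3 genes that had at most 3 counts in a group set to 3 counts there. The number of risen members was 1 without any 1 saline or AAV-GFP-MBNL1Δ library, 2 without AAV-GFP 1 and 15 without AAV-GFP 3. The lists of MHC class II (median 1.63, camera adjusted p = 0.0025, and adjusted p = 0.7 with an estimated correlation), macrophages (0.97, 0.00481, and adjusted p = 0.746 with an estimated correlation) and complement (0.96, 1.34e-04, and adjusted p = 0.592 with an estimated correlation) were called higher as well. Over all genes, as adjusted over the list alone, 0, 0 and 1 of their members rose, the last being C7. Without AAV-GFP 2 they numbered 6, 11 and 8, and without AAV-GFP 3 they numbered 5, 0 and 4. The interferon list had a camera adjusted p of 0.918, with 1 of 44 members, Ifi203, lower over all genes (−0.63, SE 0.15, adjusted p = 0.0353). With AAV-GFP 2 left out 3 members rose and 7 fell, with AAV-GFP 3 left out 1 rose and 1 fell, and 0 passed without any saline library, AAV-GFP 1 or any AAV-GFP-MBNL1Δ library.

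Adipocyte genes stood lower as a list. Of 17 measured members 8 fell, 1 rose and 8 did not pass. For the adipocyte list, adjustment over the list alone gave 11 lower and 1 higher. The adipocyte median was −1.43, with a camera adjusted p of 1.36e-10 (adjusted p = 0.592 with an estimated correlation). Scd1, a desaturase of fatty acid synthesis, fell from 753 ± 424 to 74.8 ± 53.7 CPM (−3.33, SE 0.64, adjusted p = 0.0181). Fasn, the fatty acid synthase, fell from 143 ± 60.5 to 25.5 ± 16.3 CPM (−2.49, SE 0.50, adjusted p = 0.0212). The fat cell receptor Adrb3 fell from 1.04 ± 0.513 to 0.13 ± 0.0694 CPM (−2.96, SE 0.47, adjusted p = 0.00722). Pnpla2, the lipase that starts fat breakdown and is also expressed in muscle, was the member that rose (0.40, SE 0.11, adjusted p = 0.0465; named after its value was seen), a call that ended without any 1 saline library, AAV-GFP 1 or 3 or AAV-GFP-MBNL1Δ 1 or 3 (adjusted p up to 0.175). The list median stood at −0.79, −2.54 and −2.25 in AAV-GFP-MBNL1Δ 1, 2 and 3 and at 0.56, 0.12 and −0.71 in the saline libraries, in which Xist was at 105 to 130 CPM against at most 0.0902 CPM. Without saline 1 or 2 or AAV-GFP-MBNL1Δ 2 or 3 the calls of Scd1 and Fasn ended (adjusted p up to 0.0732 and 0.0887) and 3, 3, 3 and 2 members fell; the call of Adrb3 held in all refits.

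Some heat shock, clock and glycolytic genes rose, and some endothelial genes fell, in the same libraries with Xist below 0.1 CPM. Of 19 genes of heat shock and protein quality control 7 rose and 12 did not pass, led by the HSP70 partner Dnajb1 (1.23, SE 0.15, adjusted p = 0.00274). For the heat shock list, adjustment over the list alone gave 10 higher. The heat shock median was 0.35, with a camera adjusted p of 1.6e-05 (adjusted p = 0.592 with an estimated correlation). Of 18 clock genes 5 rose and 13 did not pass. For the clock list, adjustment over the list alone gave 6 higher and 2 lower. The clock median was 0.27, with a camera adjusted p of 1.34e-04 (adjusted p = 0.592 with an estimated correlation). The 5 that rose were the transcriptional repressors Bhlhe41 (1.62, SE 0.12, adjusted p = 0.000254), Nr1d1 (1.36, SE 0.21, adjusted p = 0.00754) and Ciart (2.62, SE 0.41, adjusted p = 0.00848), the output factor Dbp (1.23, SE 0.20, adjusted p = 0.00809) and the deubiquitinase Usp2 (0.72, adjusted p = 0.0279), the last named after its value was seen. In glycolysis 3 of 27 rose: Pfkfb3, which makes the activator of phosphofructokinase, from 60.4 ± 11.9 to 335 ± 102 CPM (2.47, SE 0.24, adjusted p = 0.000854), the lactate exporter Slc16a3 (1.19, SE 0.14, adjusted p = 0.00228) and Pgk1 on chromosome X, which shares sequence with pseudogenes and is uncertain (adjusted p = 0.046). For the glycolysis list, adjustment over the list alone gave 4 higher. The glycolysis median was 0.20, with a camera adjusted p of 0.00307 (adjusted p = 0.7 with an estimated correlation). Of 20 endothelial genes Aplnr, the apelin receptor (−1.58, SE 0.14, adjusted p = 0.00065), the transcription factor Erg (−0.59, adjusted p = 0.0279) and the lipid carrier Fabp4 (−0.55, adjusted p = 0.0373) fell. For the endothelial list, adjustment over the list alone gave 7 lower. The endothelial median was −0.26, with a camera adjusted p of 2.09e-04 (adjusted p = 0.592 with an estimated correlation). Endothelial cells were also called lower as a list in AAV-GFP against saline, and not between the vectors (median −0.07, camera adjusted p = 0.284; 0.00601 without AAV-GFP 2). With any 1 library left out, Dnajb1, Bhlhe41, Nr1d1, Ciart, Dbp, Pfkfb3, Slc16a3 and Aplnr kept their calls. Erg and Usp2 lost their calls without any 1 saline or AAV-GFP-MBNL1Δ library (adjusted p up to 0.0995 and 0.117), Fabp4 without any 1 saline library, AAV-GFP 1 or AAV-GFP-MBNL1Δ 1 or 3 (up to 0.135), and Pgk1 without any 1 saline library, AAV-GFP 1 or AAV-GFP-MBNL1Δ 2 or 3 (up to 0.146). The heat shock count was 2, 1 and 3 without saline 1, 2 and 3, 4 without AAV-GFP 1 or AAV-GFP-MBNL1Δ 3, and 2 without AAV-GFP-MBNL1Δ 1 or 2. The clock and glycolysis counts were 8 and 6, and the endothelial count 12, without AAV-GFP 2, and the endothelial count 1 without any 1 saline library or AAV-GFP-MBNL1Δ 1 or 3.

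Single genes of muscle also changed against saline. The caveolar protein Cav3 rose (0.75, SE 0.09, adjusted p = 0.00181). Of 38 genes whose splicing MBNL proteins regulate, Camk2d rose (0.44, SE 0.09, adjusted p = 0.0243) and Pdlim3 fell (−0.47, SE 0.11, adjusted p = 0.0337), 1 higher and 1 lower also adjusted over the list alone, and the list was not called (camera adjusted p = 0.303). Without any 1 saline or AAV-GFP-MBNL1Δ library neither count was above 0, and without AAV-GFP 2 they were 3 higher and 11 lower. Cav3 kept its call with any 1 library left out. Camk2d lost it without any 1 saline or AAV-GFP-MBNL1Δ library (adjusted p up to 0.0996). Pdlim3 lost it without those or AAV-GFP 1 (up to 0.14). Gene counts carry no information on the splicing of these transcripts. The slow fibre list was called lower, with a median of −0.66 (camera adjusted p = 0.00137, and adjusted p = 0.7 with an estimated correlation). Of its 18 members 1 fell, or 3 adjusted over the list alone: Pln, the inhibitor of the calcium pump, named after its value was seen (−2.11, SE 0.40, adjusted p = 0.0175). The call of Pln ended without any 1 AAV-GFP-MBNL1Δ library (up to 0.0714), and 6 and 3 members fell without AAV-GFP 2 and 3. Splicing factors (camera adjusted p = 0.0245, and adjusted p = 0.592 with an estimated correlation) and Schwann cells and nerve (0.0179, and adjusted p = 0.7 with an estimated correlation) were called lower too. Red blood cells (0.0095, and adjusted p = 0.592 with an estimated correlation) and cytosolic ribosomal proteins (0.0162, and adjusted p = 0.799 with an estimated correlation) were called higher. Of these 4 calls, that of splicing factors ended without saline 2 (0.0721), that of Schwann cells without saline 3 or AAV-GFP-MBNL1Δ 2 or 3 (up to 0.102) and that of ribosomal proteins without AAV-GFP-MBNL1Δ 2 (0.174).

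**Figure D3:**
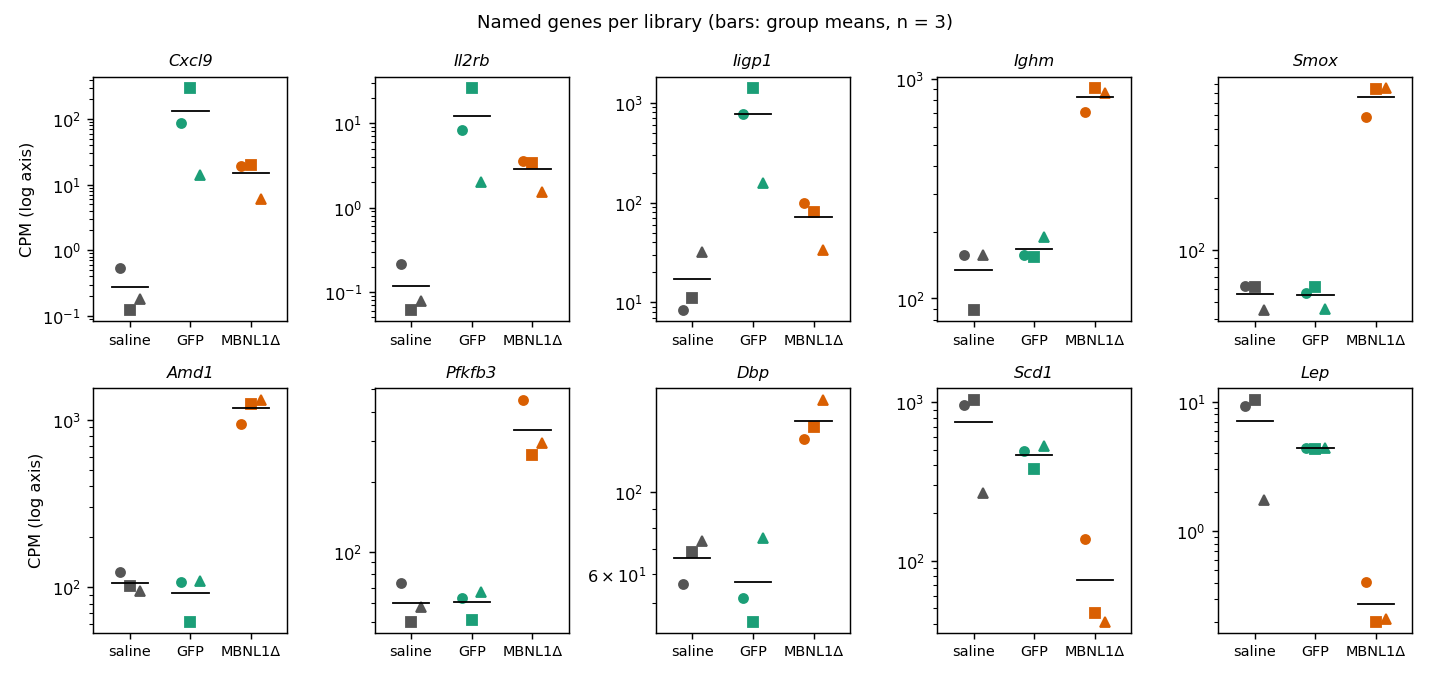
CPM (log axis) of 10 genes in each library, with circles, squares and triangles for replicates 1, 2 and 3, bars for the mean of 3 libraries where all 3 are above 0, and groups in grey (saline), green (AAV-GFP) and orange (AAV-GFP-MBNL1Δ). Cxcl9, Il2rb and Iigp1 spread widely over the AAV-GFP libraries, and Pfkfb3 averaged 335 CPM in AAV-GFP-MBNL1Δ against 60.4 CPM in saline.

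AAV-GFP-MBNL1Δ against AAV-GFP, the comparison between the 2 vectors, gave 2006 genes that rose and 1908 that fell. The spread behind these calls was shared with the saline libraries. With only the 2 vector groups fitted, 788 genes rose and 371 fell. Of the immune lists that had been high in AAV-GFP, most were called lower in AAV-GFP-MBNL1Δ. Those of B cells (camera adjusted p = 0.314), complement (camera adjusted p = 0.29) and granulocytes and mast cells (camera adjusted p = 0.168) were not. Of 44 interferon-stimulated genes 37 fell and 7 did not pass. For the interferon list, adjustment over the list alone gave 42 lower here and 43 higher in AAV-GFP against saline, where 0 passed over all genes. Adjustment over all genes depends on the other genes of a comparison, which held 3914 calls here and 0 there. The higher counts over all genes here are thus no measure of a larger immune difference between the vectors than against saline. The interferon median was −2.07, with a camera adjusted p of 4.65e-20 (adjusted p = 0.592 with an estimated correlation). Irgm2 fell from 432 ± 283 to 37.4 ± 16.3 CPM (−3.53, SE 0.68, adjusted p = 0.0135) and Iigp1 from 780 ± 622 to 71.2 ± 34.1 CPM (−3.45, SE 0.86, adjusted p = 0.0302). Ifi44 (−2.97, SE 0.41, adjusted p = 0.00395) and Cmpk2, a mitochondrial nucleotide kinase that interferon induces (−1.26, SE 0.20, adjusted p = 0.0065), fell too. In MHC class I presentation 17 of 19 fell, among them the peptide transporter Tap1 (−2.87, SE 0.69, adjusted p = 0.0271), and in MHC class II 9 of 16 fell, among them Xcr1 of cross-presenting dendritic cells (−2.80, SE 0.55, adjusted p = 0.0135). For the MHC class II list, adjustment over the list alone gave 14 lower. The MHC class II list had a camera adjusted p of 9.51e-05 (adjusted p = 0.687 with an estimated correlation). For the MHC class I list, adjustment over the list alone gave 19 lower. The MHC class I median was −2.28, with a camera adjusted p of 2.39e-08 (adjusted p = 0.592 with an estimated correlation). Of 25 chemokines and cytokines 12 fell and 1 rose; the member that rose, named after its value was seen, was Cxcl14 (0.89, SE 0.25, adjusted p = 0.04). For the chemokine list, adjustment over the list alone gave 21 lower and 1 higher. The chemokine list had a camera adjusted p of 3.9e-06 (adjusted p = 0.664 with an estimated correlation). Of 27 macrophage genes 6 fell, and Mmp12, the macrophage elastase, fell from 6.22 ± 3.71 to 0.235 ± 0.0967 CPM (−4.73, SE 0.89, adjusted p = 0.0125). For the macrophage list, adjustment over the list alone gave 24 lower. The macrophage list had a camera adjusted p of 6.02e-06 (adjusted p = 0.69 with an estimated correlation).

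Other immune and growth-related lists were lower in the same comparison. Of 26 cell cycle genes 8 fell. For the cell cycle list, adjustment over the list alone gave 22 lower. The cell cycle median was −2.28, with a camera adjusted p of 1.36e-04 (adjusted p = 0.7 with an estimated correlation). In the unfolded protein response 6 of 23 fell and 1 rose, with the asparagine synthetase Asns lower (−1.22, SE 0.20, adjusted p = 0.00644) and Chac1, which degrades glutathione, higher (1.61, SE 0.38, adjusted p = 0.0255). For the unfolded protein list, adjustment over the list alone gave 13 lower and 2 higher. The unfolded protein list had a camera adjusted p of 0.00772 (adjusted p = 0.687 with an estimated correlation). T-cell genes had a median of −1.86 (camera adjusted p = 1.77e-04, and adjusted p = 0.7 with an estimated correlation), but only Thy1 (−0.83, SE 0.18, adjusted p = 0.0193) and Gzma (−3.24, SE 0.90, adjusted p = 0.0394) fell among 30 (1 adjusted over the list alone), and the list lost its call without AAV-GFP 2 (adjusted p = 0.06). Of 17 adipocyte genes 9 fell and 1, Pnpla2 (0.51, SE 0.11, adjusted p = 0.0147), rose, with Lep at 4.37 ± 0.0855 CPM in AAV-GFP and 0.272 ± 0.116 CPM in AAV-GFP-MBNL1Δ (−3.99, SE 0.66, adjusted p = 0.00828). For the adipocyte list, adjustment over the list alone gave 12 lower and 1 higher. The adipocyte median was −1.66, with a camera adjusted p of 1.73e-05 (adjusted p = 0.592 with an estimated correlation). In the libraries compared, Xist was at 106 to 136 CPM in AAV-GFP and at most 0.0902 CPM in AAV-GFP-MBNL1Δ, and AAV-GFP 2, with the lowest share of abundant and mitochondrial transcripts, had the highest immune values. Ighm went the other way, from 167 ± 19.3 to 825 ± 104 CPM (2.30, SE 0.23, adjusted p = 0.00103).

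Single libraries weighed on these immune calls, among them saline libraries, which enter this comparison only through the shared fit. Without AAV-GFP-MBNL1Δ 1, 2 and 3 the interferon members that fell numbered 17, 16 and 6, those of MHC class I 0, 0 and 0, those of the chemokines 2, 2 and 1 and those of the macrophages and the cell cycle 0, 0 and 0. Without AAV-GFP 3, whose immune values were the lowest of its group, they numbered 43, 19, 24, 27 and 22 and all 30 T-cell genes fell, against at most 1 in the other 8 refits. Without saline 1, 2 or 3 the MHC class I members that fell numbered 5, 2 and 7, and without AAV-GFP 1 or 2 they numbered 7 and 8. Chemokines numbered 4 or 5 and cell cycle genes 0 in each of these refits, and macrophage genes 0 without any 1 saline library and 3 without AAV-GFP 2. In MHC class II the number was 15 without AAV-GFP 3 and between 0 and 3 without any other library. In the adipocyte list it was 3, 5, 3 and 1 without AAV-GFP 1 or 2 or AAV-GFP-MBNL1Δ 2 or 3 and 6 without saline 1 or 2. In the unfolded protein response it was 13 without AAV-GFP 3 and 1 to 3 without any other library. Ifi44, Cmpk2, Asns, Lep and Ighm kept their calls in all 9 refits. Irgm2, Mmp12, Xcr1 and Pnpla2 lost theirs without AAV-GFP-MBNL1Δ 3 (adjusted p = 0.0617, 0.0648, 0.065 and 0.0689), and Thy1 and Chac1 without any 1 AAV-GFP-MBNL1Δ library (up to 0.077 and 0.0803). Tap1 lost it without those or AAV-GFP 2 (up to 0.101), Iigp1 without those, AAV-GFP 1, AAV-GFP 2 or saline 2 (up to 0.108), and Gzma without any library other than AAV-GFP 3 (up to 0.128). Cxcl14 lost it without saline 2, AAV-GFP 1 or any 1 AAV-GFP-MBNL1Δ library (up to 0.113).

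The lists of glycolysis, calcium handling, fast fibre and clock genes stood higher in AAV-GFP-MBNL1Δ than in AAV-GFP. AAV-GFP 2 was the lowest of its group in each (−0.62, −0.68, −0.68 and −0.43 against the saline mean, in that order), and without it the lists called higher went from 11 to 8, these 4 among the 8. Shares of a library do not separate levels within muscle fibres from the mix of cells, which was not measured. Against saline, fast fibre (camera adjusted p = 0.14) and calcium handling (camera adjusted p = 0.306) were not called. Slow fibre genes had a median of −0.65 between the vectors and were not called as a list (camera adjusted p = 0.0696), although they were without saline 3, AAV-GFP 2 or AAV-GFP-MBNL1Δ 1 or 3 (0.0383, 2.24e-04, 0.0383 and 0.0399). Of 27 glycolysis and glycogen genes 11 rose and 1 fell, led by Slc16a3 (1.54, SE 0.14, adjusted p = 0.000738) and Pfkfb3 (2.47, SE 0.24, adjusted p = 0.000905); the member that fell, named after its value was seen, was the glucose transporter Slc2a1 (−0.85, adjusted p = 0.044). For the glycolysis list, adjustment over the list alone gave 16 higher and 1 lower. The glycolysis median was 0.48, with a camera adjusted p of 3.04e-08 (adjusted p = 0.592 with an estimated correlation). In excitation-contraction coupling 10 of 24 rose, among them Sypl2, a protein of the triad membrane (0.87, SE 0.14, adjusted p = 0.00665), and the junctophilins Jph2 (0.67, SE 0.12, adjusted p = 0.0102) and Jph1 (0.86, SE 0.18, adjusted p = 0.0169). For the calcium handling list, adjustment over the list alone gave 13 higher and 1 lower. The calcium handling median was 0.38, with a camera adjusted p of 1.47e-05 (adjusted p = 0.592 with an estimated correlation). Of 18 fast fibre genes 5 rose: the light chain kinase Mylk2 (1.24, SE 0.24, adjusted p = 0.0127), Myoz1, Myl1, Tnni2 and, named after its value was seen, Pgam2. For the fast fibre list, adjustment over the list alone gave 5 higher. The fast fibre median was 0.55, with a camera adjusted p of 9.59e-06 (adjusted p = 0.592 with an estimated correlation). Of 18 clock genes 9 rose and 1 fell, with Bhlhe41 (1.64, SE 0.12, adjusted p = 0.000231) and Dbp (1.45, SE 0.20, adjusted p = 0.00372) higher and Npas2, named after its value was seen, lower (−0.75, adjusted p = 0.043). For the clock list, adjustment over the list alone gave 11 higher and 2 lower. The clock median was 0.47, with a camera adjusted p of 4.97e-08 (adjusted p = 0.592 with an estimated correlation). Of 19 heat shock genes 9 rose. For the heat shock list, adjustment over the list alone gave 9 higher. The heat shock list had a camera adjusted p of 5.54e-04 (adjusted p = 0.592 with an estimated correlation). Mstn, the inhibitor of muscle growth myostatin, rose from 46.4 ± 10.9 to 141 ± 10.8 CPM (1.60, SE 0.21, adjusted p = 0.00305) and the myogenic factor Myod1 from 27.4 ± 1.03 to 40.4 ± 4.27 CPM (0.56, SE 0.10, adjusted p = 0.00779). Both belong to the list of muscle regeneration, of whose 23 members 5 rose and 2 fell, the same adjusted over the list alone, and which was not called (camera adjusted p = 0.224; 0.0295 without AAV-GFP 2). The others, named after their values were seen, were Sgca (0.65, SE 0.14, adjusted p = 0.0179), Pax7 (0.78, SE 0.19, adjusted p = 0.0254) and Myf6 (0.33, SE 0.09, adjusted p = 0.0386), which rose, and Myog (−0.97, SE 0.20, adjusted p = 0.0167) and Vim (−1.41, SE 0.35, adjusted p = 0.0281), which fell. The calls of Sgca and Myog ended without AAV-GFP-MBNL1Δ 2 or 3 (up to 0.0788 and 0.0703), that of Pax7 without any 1 AAV-GFP-MBNL1Δ library or AAV-GFP 1 (up to 0.103), that of Vim without any 1 AAV-GFP-MBNL1Δ library or saline 2 (up to 0.107), and that of Myf6 without any library other than AAV-GFP 2 or AAV-GFP-MBNL1Δ 1 (up to 0.133).

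Of the 38 genes whose splicing MBNL proteins regulate, 6 rose and 2 fell in AAV-GFP-MBNL1Δ against AAV-GFP. For the MBNL-regulated list, adjustment over the list alone gave 6 higher and 2 lower. The MBNL-regulated median was 0.19, with a camera adjusted p of 0.011 (adjusted p = 0.7 with an estimated correlation). Phka1, a phosphorylase kinase subunit on chromosome X, rose by 0.86 (SE 0.18, adjusted p = 0.0172) and the transcription factor Nfix by 0.71 (SE 0.17, adjusted p = 0.023), while Pdlim3 (−0.54, SE 0.11, adjusted p = 0.0153) and Ppp1r12a (−0.30, SE 0.06, adjusted p = 0.0174) fell. Mbnl1, to which reads of the vector could be assigned, is itself 1 of the 6. Here too, levels within muscle fibres were not separated from the mix of cells. The list lost its call without AAV-GFP 2 (adjusted p = 0.218), the library in which its median was −0.59 against −0.17 and −0.13 in AAV-GFP 1 and 3, and the number of risen members was 3, 2 and 3 without saline 1, 2 and 3, 2 without AAV-GFP 1 and 1, 3 and 0 without AAV-GFP-MBNL1Δ 1, 2 and 3. Phka1 and Pdlim3 lost their calls without AAV-GFP-MBNL1Δ 2 or 3 (adjusted p up to 0.0776 and 0.0813), Nfix without AAV-GFP-MBNL1Δ 1 or 3 (up to 0.0943) and Ppp1r12a without those or AAV-GFP 1 (up to 0.0725). Of the other genes named in this comparison, Slc16a3, Pfkfb3, Sypl2, Bhlhe41, Dbp, Mstn and Myod1 kept their calls in all 9 refits, and Jph2, Jph1 and Mylk2 lost theirs without AAV-GFP-MBNL1Δ 3 (adjusted p = 0.0537, 0.0734 and 0.06). Slc2a1, Npas2 and Tnni2 lost theirs without any library other than AAV-GFP 2 or 3 (up to 0.132, 0.15 and 0.132), Pgam2 without any other than AAV-GFP 3 (up to 0.148), Myoz1 without AAV-GFP 1 or any 1 AAV-GFP-MBNL1Δ library (up to 0.0881) and Myl1 without AAV-GFP 1 or AAV-GFP-MBNL1Δ 2 or 3 (up to 0.0889). The fast fibre count was 3 without any 1 saline library, 1 without AAV-GFP 1, 8 without AAV-GFP 3 and 2, 1 and 0 without AAV-GFP-MBNL1Δ 1, 2 and 3. The heat shock count was 4 or 5 without saline 1 or 2, AAV-GFP 1 or any 1 AAV-GFP-MBNL1Δ library, and the clock count 5 without AAV-GFP-MBNL1Δ 3. Glycolytic members that rose numbered 7, 2 and 2 without AAV-GFP-MBNL1Δ 1, 2 and 3, 7 without saline 1 and 4 without AAV-GFP 1. Those of calcium handling numbered 4, 3 and 1 without AAV-GFP-MBNL1Δ 1, 2 and 3, 4, 4 and 6 without saline 1, 2 and 3, and 3 without AAV-GFP 1. Over all genes, of which the refits tested 18682 to 19076 and the fit to 9 libraries 18514, the counts were 1328 and 959, 1255 and 854, and 1502 and 1106 higher and lower without saline 1, 2 and 3, 1011 and 817 without AAV-GFP 1, 2380 and 4269 without AAV-GFP 3, and 1003 and 552, 1148 and 494, and 556 and 270 without AAV-GFP-MBNL1Δ 1, 2 and 3.

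The effects of the 2 vectors against saline were compared, with the same 3 saline libraries in both. With edgeR no gene could be shared, since AAV-GFP against saline had 0 calls (4065 genes had an unadjusted p under 0.05); DESeq2 called 258 genes in both in the same direction, and without AAV-GFP 2 or 3 edgeR gave 3 and 351. The covariance of the log2 fold changes over 18514 genes was 0.743 against 0.0631 in 50 simulations of unchanged groups against those controls, a difference of 0.68, with a correlation across genes of 0.71 against 0.49; genes are not independent replicates. The direction was the same in 57.4% of genes against 66.6% in the simulation. Genes called for AAV-GFP-MBNL1Δ against saline and against AAV-GFP in the same direction numbered 1338 (748 higher and 590 lower, with 6 in opposite directions). The simulation gave 0.02, a value fixed near 0 because its groups did not differ, so it cannot weigh this number. Independent lists would share 95.6 higher and 87.8 lower genes, but both comparisons hold the same AAV-GFP-MBNL1Δ libraries. Those are also the only libraries with Xist near 0, so vector and sex cannot be told apart here. Over all tested genes the covariance of that pair was 0.0494 against 0.0642 in the simulation (difference −0.0148), with a correlation of 0.07 against 0.5. Part of any excess may come from the shared libraries, since 3 libraries cannot be split so that each part keeps 2.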

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

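The tests of a difference in sex behind the autosomal calls, of the amount of vector and of mixed Y-linked reads were chosen after the result was seen, as was the bound of 10 reads in the test of lymph node genes. The reads of Eif2s3y, Uty and Ddx3y were looked at because Y-linked genes, measured as a check of the samples and also counted among the tested genes, stood above their level in saline. Summed over these 3 genes, the lowest AAV-GFP-MBNL1Δ library held 161 CPM and AAV-GFP 1 held 4.43 CPM.

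The AAV-GFP-MBNL1Δ libraries differed from the other 6 in sex-linked genes, and the values are those of animals of the other sex. Xist was near 0 and Y-linked genes were high in these libraries. All 4 X-linked genes with a Y-linked partner (Kdm6a, Kdm5c, Eif2s3x and Ddx3x) were lower in each of the 3 AAV-GFP-MBNL1Δ libraries than in each of the 6 others. The tables offer no value against a difference in sex as a source of the autosomal calls, since 0 of the 9 libraries had sex-linked genes that did not follow the split, and sex and vector cannot be told apart. For linked genomic differences between the mice, the prediction written before was a densest window of 100 tested genes above 95% of 1000 shuffles. It was not met. That window (chromosome 8, 72424176 to 84670483) held 23 called genes, the value that 95% of the shuffles stayed at or under (permutation p = 0.0599). Such differences stay open too, since a window at this limit does not exclude them. The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. The real split and the highest other gave 0 and 0 calls for AAV-GFP against saline (10 of 10 splits as large), 1734 and 0 for AAV-GFP-MBNL1Δ against saline (1 of 10) and 3914 and 0 for AAV-GFP-MBNL1Δ against AAV-GFP (1 of 10).

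Immune genes differed among the 3 AAV-GFP libraries. The tables argue against scaling between libraries as the cause, since the range of the interferon list over these libraries was at least 1.85 under 4 scalings, against at most 0.38 over the saline libraries. Lymph node tissue carried along with the muscle may contribute and stays open. Against saline the median of 9 lymph node genes lay at 3.51 and that of 9 cytotoxic genes at 6.83, a difference of −3.31 (exact permutation p = 0.0101 over 48620 splits of the genes). That compares groups and not the 3 libraries, and it rests on saline counts with a median of 4 reads per library, under the bound of 10. The amount of vector that reached the muscle may differ and stays open, as 0 features of the tables are named GFP. A difference between the animals in their response was not tested.

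AAV-GFP 1 held Y-linked reads that AAV-GFP 2 and 3 did not hold at that level. RNA or reads of the AAV-GFP-MBNL1Δ libraries mixed into it would give the same share for each gene, but the shares of the AAV-GFP-MBNL1Δ level, after the saline mean was subtracted from AAV-GFP 1, were 2.06% for Eif2s3y, 2.58% for Uty, 2.39% for Ddx3y and 0.442% for Kdm5d, a ratio of highest to lowest of 5.85. Kdm5d had 5 counts (95% Poisson interval 1.62 to 11.7) where the median share would give 23.7. Without Kdm5d the ratio was 1.25, so the case against mixing rests on that 1 gene, and mixing with RNA of another male source could remain. No biological explanation was tested.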

How the results depend on the processing

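Limma-voom with quality weights per library and the fit to autosomal genes were chosen after seeing the data; the cause of the changes was not tested. For AAV-GFP against saline, edgeR called 0 genes, DESeq2 1619 higher and 86 lower, quality weights 3078 and 2386, and the leave-one-out fits 0 to 2907 higher and 0 to 355 lower. For AAV-GFP-MBNL1Δ against saline (882 and 852), DESeq2 gave 1600 and 1289, the fold threshold 117 and 75, the 2 groups alone 2303 and 2281, quality weights 2854 and 2604, and the leave-one-out fits 286 to 1933 and 214 to 2114. For AAV-GFP-MBNL1Δ against AAV-GFP (2006 and 1908), the fold threshold gave 163 and 57, the 2 groups alone 788 and 371, quality weights 4442 and 4852, and the leave-one-out fits 556 to 2380 and 270 to 4269; lower genes numbered 1133 with no low-count filter, 3006 with DESeq2 and 1260 with limma-voom. Of the genes named in the texts and called between the vectors, 49 lost the call with the fold threshold, 29 with the 2 groups alone and 18 with no low-count filter. The named genes whose status stayed the same, called or not, numbered 25, 45 and 56. For AAV-GFP-MBNL1Δ against saline, 32 named genes lost the call with the fold threshold, 2 with the 2 groups alone and 13 with no low-count filter. Genes called for both vectors against saline in the same direction, 0 with edgeR, numbered 258 with DESeq2, 1092 with quality weights and 0 to 351 in the leave-one-out fits. Of 120 list tests 62 passed with the preset correlation, 59 to 68 in the leave-one-out fits, and 0 with an estimated correlation or with fry's directional test. Fry's mixed test, which ignores direction, passed 3, 22 and 25 lists for AAV-GFP against saline, AAV-GFP-MBNL1Δ against saline and AAV-GFP-MBNL1Δ against AAV-GFP.

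The samples share only a number. Correlations of same-numbered libraries were taken on log2 levels after each gene's group mean was subtracted, so they compare deviations and not expression itself. They were 0.07, −0.08 and −0.07 for AAV-GFP and saline, −0.01, −0.04 and −0.03 for AAV-GFP-MBNL1Δ and saline and 0.07, 0.17 and 0.45 for both vectors. Not every sample correlates best with its own number. With the replicate block, 99 genes were higher in AAV-GFP than in saline, 69 genes were shared by both vectors against saline, 63 list tests passed and 12 named genes lost their call between the vectors.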

Other observations

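The genes of polyamine metabolism were chosen after their values were seen, and the test of the clock phase before. Odc1, the first enzyme of polyamine synthesis, rose from 47.1 ± 1.53 CPM in saline to 293 ± 41.7 CPM in AAV-GFP-MBNL1Δ (2.64, SE 0.18, adjusted p = 0.000206), and Smox (chromosome 2, 131491496 to 131525922), which oxidizes spermine, from 56.1 ± 9.71 to 762 ± 155 CPM (3.76, SE 0.22, adjusted p = 0.000108). Amd1, whose enzyme supplies the aminopropyl groups, rose by 3.45 (SE 0.25, adjusted p = 0.000263) and is uncertain because it shares reads with Amd2, which rose by 3.44. Of 12 genes of this pathway 5 rose, the fifth being Sms (0.74, SE 0.15, adjusted p = 0.0197), which lost its call without any 1 saline or AAV-GFP-MBNL1Δ library (adjusted p up to 0.0754), and 0 fell; Odc1, Amd1 and Smox kept theirs with any 1 library left out. Odc1 and Amd1 are known to respond to androgens, so a difference in sex between the groups may contribute, with 0 of the 9 libraries able to separate it from the vector.

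Clock genes differed between AAV-GFP-MBNL1Δ and saline. A different phase of the clock at tissue collection is a candidate explanation. The prediction written before was a median below 0 for genes peaking with Arntl, with genes peaking with Dbp higher. It was met: the medians of the log2 fold change were −0.23 and 0.97. The members of the first set went both ways (Npas2 −0.79, Arntl −0.67, Cry1 −0.23, Clock 0.10, Nfil3 0.33), a condition that was not part of that prediction. With members in both directions, the phase cannot be told apart from other causes.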
